A study of Homo sapiens with 82 samples.

How the data were processed

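The intensity values were taken as deposited by the authors, on a linear scale, and had been computed with the robust multi-array average (RMA) method per the submitters' processing notes. The version of that method is not given in the sources used here, and neither is which arrays were normalized together. Total RNA from cells grown in DMEM with serum was labelled with biotin and hybridised to U133 Plus 2.0 arrays. All values were put on a log2 scale, and 0 columns of values were left unused. The array medians in the first set spanned 30.3 to 33.7, so no further normalization was applied.

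Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none here. Symbols were updated through the Entrez identifier for 41043 probe sets. Each gene was represented by its probe set with the highest mean, which gave 19775 genes. A gene was tested if its mean in at least 1 group reached the median of the first set, 4.99 on the log2 scale or an intensity of 31.8, and 13196 genes passed.

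Models were fitted with limma 3.58.1 in R 4.3.3, with input read by the package data.table, version 1.17.8. Each set had 1 mean per group, with 35 residual degrees of freedom in the first set and 19 in the second. P-values were moderated with a prior of 4.85 degrees of freedom in the first set and adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. The difference of the responses between the lines was fitted as an interaction. A list of genes was tested with camera in limma at the preset correlation of 0.01, and again with a correlation estimated from the residuals. There were 32 lists with 548 members, of which 439 were tested, fixed together with the groups and comparisons before the data were examined.

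Named genes follow a rule set in advance. For the lines, for each agent at 5 µM and 48 h in each line, and for CsA against NIM811 at 48 h, these are the up to 10 largest rises and falls among called genes whose arrays do not overlap. For every other comparison they are the up to 3 largest of each, and for each list described its up to 4 members with the largest change. The text may name fewer, from the largest change down. In addition 7 genes are always given: PPIA, PPIB, PPIF, RCAN1, HSPA5, DDIT3 and HMGCS1.

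The sets were planned to be fitted together with a term for the set. The row identifiers of the second set did not go with its values, so each set was fitted on its own and no term for the set was used. This was checked on genes with 2 probe sets: over 3696 genes, the difference between the lines had a correlation between the probe sets of 0.650 in the first set and 0.0339 in the second. Of the 33 comparisons planned, CsA 1 µM at 24 h in Clone A had no control of its time in its set and was set against the control of 48 h.

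Whether the replicate numbers pair the arrays was checked on the residuals of the fit. In the first set 25 of 52 pairs with the same number had a correlation above 0.1, with a median of 0.0737, against 31 of 104 with different numbers, and the arrays were treated as unpaired. In Clone A at 48 h the share was higher, 7 of 9 against 6 of 18. In Clone A at 12 h the pairs of CsA and NIM811 arrays with the same number had 0.467 to 0.787. There replicates 1 and 2 also correlated across the agents, at 0.541 and 0.322. In the second set all 9 pairs of the Huh7 arrays passed, and blocked counts are given beside the results there that they change by over 1.5 times. In Clone A of that set 1 of 2 pairs passed, so pairing was not shown there. The arrays at 1 µM share numbers only with others at that dose, and the 3 pairs within Huh7 passed, at 0.666 to 0.760.

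The fit was tested on simulated data with 200 of 13196 genes changed. For CsA in Huh7 at 48 h it called 50.7% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 3.77% of its calls were false. For CsA in Huh7 at 24 h, with 2 arrays, the values were 28.4%, 80.6% and 98.5%, with 3.50% false. For NIM811 in Clone A at 12 h they were 44.8%, 83.6% and 97.0%, with 3.85% false. When 1 list was shifted by 0.5, camera gave it an adjusted p of 9.91e-36 and called 0 of the others. The simulated noise was independent between arrays and genes, with the same spread of a gene in all groups. These rates therefore do not cover data with correlated arrays or genes, such as the real arrays at 48 h. The overlap of CsA and NIM811 was set against 100 simulated data sets with no effect that kept the shared controls.

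Alternatives tried were other filters on dim genes, centring each array on its median, quantile normalization, the mean of the probe sets of a gene, all probe sets, a trend and robust prior, replicate numbers as blocks and only the arrays of the groups compared. Others were each line fitted alone and each array left out in turn. Added later were a score of 14 matrix genes minus 15 hepatocyte genes as a covariate, the ratio of the beta-actin probe sets as a covariate, array weights, the mean of 24 and 48 h, the interaction at each time, a dim filter in the second set and blocks for its Huh7 arrays at 1 µM.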

Results

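Gene expression was measured on 82 Affymetrix U133 Plus 2.0 arrays hybridised with RNA from a pair of human hepatoma cultures. Huh7 is an established hepatocellular carcinoma line. Clone A is Huh7 carrying a genotype 1B hepatitis C virus replicon, a self-replicating viral RNA that makes no infectious particles. Cells were harvested without drug or with cyclosporin A (CsA), which binds cyclophilins and through them inhibits calcineurin, or with NIM811, a CsA analogue that binds cyclophilins without inhibiting calcineurin. Both agents were given at 5 µM for 12, 24 or 48 h. A dose of 1 µM was given for 48 h in Huh7, and in Clone A for 24 h with CsA and for 48 h with NIM811. The arrays fell into 22 groups by line, agent, dose and time.

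The table held 2 sets of arrays. The first set of 53 arrays had a value for all 54675 probe sets, with array medians of 30.3 to 33.7 intensity units, and covered the 18 groups of untreated and 5 µM cells at 3 arrays each, except for Huh7 with CsA at 24 h, which had 2. The second set of 29 arrays had 20844 values an array, with medians of 206 to 240, and covered 10 groups of cells at 3 arrays each, except for Clone A with NIM811 5 µM at 48 h, which had 2. In the second set the row identifiers did not go with the values: the row of albumin, the main protein made by hepatocytes, had a median of 322 there and of 22561 in the first set, and levels across rows had a correlation of -0.07 with the first set. Gene names are therefore given for the first set alone, and the second set is reported as counts of rows. The number of arrays limits the precision of every value, and the p-values measure the spread between these arrays, since the labels do not say whether the arrays of a group came from separate cultures.

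Untreated Clone A and Huh7 cells differed in many genes. Clone A was the only line with the replicon, so its effect cannot be told apart from any other difference between the lines. PLA1A, a phospholipase acting on phosphatidylserine, was 17.6-fold higher in Clone A over the mean of the 3 times, a log2 difference of 4.14 ± 0.62 (SE). TMSB4X, which encodes the actin-binding thymosin beta-4, was higher by 3.72 ± 0.31, and EREG, a ligand of the epidermal growth factor receptor, by 3.56 ± 0.31. CES1, the main carboxylesterase of liver, was 24.0-fold lower, a log2 difference of -4.59 ± 0.15. NPTX2, a neuronal pentraxin, differed by -4.17 ± 0.34, CPE, a carboxypeptidase that processes peptide hormones, by -4.07 ± 0.11, and B3GNT5, an enzyme of glycosphingolipid synthesis, by -3.81 ± 0.09. Among the next largest rises were TMEM176A, CAPRIN2 and the aldo-keto reductase AKR1C2, and among the next largest falls were COL14A1 and COL2A1, both collagens.

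Of 13196 genes tested, limma called 6422 between the untreated lines at an adjusted p under 0.05, 3041 higher and 3381 lower in Clone A, with 223 and 241 of them changed at least 2-fold. Genes of mitosis were lower in Clone A: 16 of 20 fell and none rose (18 adjusted over the list alone), among them PLK1, a mitotic kinase, by -0.90 ± 0.17, and CCNA2, cyclin A2, by -0.72 ± 0.15 (camera adjusted p = 0.00162, but adjusted p = 0.772 with an estimated correlation). In the list of DNA replication genes, 13 of 21 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.00614, but adjusted p = 0.772 with an estimated correlation). CCNE1, cyclin E1, changed by -0.90 ± 0.13. In the respiratory chain list, 9 of 13 genes fell and 2 rose, the same counts when adjusted over the list alone, with the cytochrome oxidase subunit COX5A at -0.75 ± 0.07 (adjusted p = 0.00162, but adjusted p = 0.772 with an estimated correlation). Of the 16 autophagy and lysosome genes, 11 rose and none fell (11 and 1 adjusted over the list alone), including the sialidase gene NEU1 by 1.58 ± 0.21 and the protease CTSL 2.82-fold (adjusted p = 0.00162, but adjusted p = 0.772 with an estimated correlation). The hepatocyte function list was not called: ARG1, the arginase of the urea cycle, fell by 2.51 ± 0.37, while CPS1, which starts that cycle, rose by 2.04 ± 0.23. In the interferon-stimulated list, which holds the genes that viral RNA sensing can induce, 2 of 14 genes were higher and 6 lower, with an adjusted p of 0.297 for the list.

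Taken at each time on its own, 4549 genes differed between the untreated lines at 12 h, 2186 at 24 h and 2967 at 48 h. Of these 1667 were higher and 2882 lower in Clone A at 12 h, 1180 and 1006 at 24 h, and 1611 and 1356 at 48 h. In this fit the excess of lower genes over the mean of the times was seen at 12 h and not later. At 48 h the direction depended on scaling: the split was 1406 and 1457 with median centring and 1476 and 1622 with quantile normalization. At 12 h the largest rises were PLA1A at 4.73 ± 1.07 and ACTN3, a muscle-type actinin, at 4.37 ± 0.62, and the largest fall was CES1 at -4.78 ± 0.27. At 24 h MT1M, a metallothionein that binds zinc and copper, was the largest rise at 4.73 ± 0.75. At 48 h TMSB4X at 4.04 ± 0.55 and EREG at 4.03 ± 0.54 led the rises, and CPE at -4.28 ± 0.20 the falls. The groups did not overlap for 4263, 2163 and 2498 of the called genes, and for 50.0%, 44.9% and 30.0% of all genes, where chance gives 10% for 3 arrays against 3. A fit of only the 6 arrays compared gave 3332 genes at 24 h and 319 at 48 h.

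In Huh7 at 12 h, CsA raised metallothioneins, whose products bind zinc and copper. MT1M rose by 3.90 ± 0.75, from a mean log2 intensity of 5.69 in controls (SD 1.73, n = 3) to 9.59 (SD 0.02, n = 3), and MT1E and MT1X rose by 3.21 ± 0.68 and 3.19 ± 0.64. SLC39A10, a zinc importer, fell by 1.52 ± 0.37 and DGAT2, which makes triglycerides, by 1.27 ± 0.29. Genes of transport from the endoplasmic reticulum (ER) to the Golgi rose, 8 of 19 and none lower (13 adjusted over the list alone), led by SEC24D, a vesicle coat subunit, at 1.19 ± 0.24 and ARFGAP3, a Golgi regulator, at 1.15 ± 0.17; the list had a camera adjusted p of 7.12e-20, and of 2.28e-04 with an estimated correlation. ER chaperones and genes of the unfolded protein response had 4 of 16 higher (10 and 1 lower adjusted over the list alone; adjusted p = 1.14e-13, but adjusted p = 0.171 with an estimated correlation). SDF2L1 rose by 1.19 ± 0.19 and CRELD2 2.29-fold, both ER proteins. Limma called 117 genes, 104 higher and 13 lower, and all 117 were free of overlap between the groups, against 20.6% of all genes and 10% by chance. Signs of RNA quality differed too. The log2 ratio of the GAPDH probe sets was 0.0819 to 0.331 in controls and at most 0.0261 with CsA, and the mean beta-actin ratio was 0.791 and 0.450. Without 1 array the count lay between 52, without CsA replicate 3, and 101, without control replicate 1, and it moved by over 1.5 times for 4 of the 6 arrays.

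At 24 h in Huh7, CsA raised the genes that the transcription factor ATF4 controls when amino acids are short. In that list 14 of 19 rose and none fell (18 adjusted over the list alone; adjusted p = 3.26e-22, and 0.0293 with an estimated correlation). CHAC1, which degrades glutathione, rose by 2.57 ± 0.53, DDIT4, an inhibitor of growth signalling, by 2.50 ± 0.63, and ASNS, asparagine synthetase, by 2.43 ± 0.48. Genes of mitosis fell, 8 of 20 with none higher (18 adjusted over the list alone), with the topoisomerase TOP2A at -1.30 ± 0.19 and the kinesin KIF20A at -1.13 ± 0.29 (adjusted p = 3.26e-22, and 0.0452 with an estimated correlation). Aminoacyl-tRNA synthetases, which load amino acids onto tRNA, had 7 of 14 higher (11 and 1 lower adjusted over the list alone; adjusted p = 6.47e-09, and 0.0293 with an estimated correlation). WARS1 rose by 1.54 ± 0.20. Of 16 ER chaperone genes 5 rose (11 adjusted over the list alone), with the co-chaperone DNAJB9 at 1.46 ± 0.24 (adjusted p = 2e-10, but adjusted p = 0.229 with an estimated correlation). Of 19 ER to Golgi genes 5 rose (9 adjusted over the list alone; adjusted p = 2.15e-07, and 0.0452 with an estimated correlation). The largest single changes were MT1M at 3.28 ± 0.84 and MT1E at 2.80 ± 0.77, and HP, the plasma protein haptoglobin, at -1.72 ± 0.46. Limma called 403 genes, 272 higher and 131 lower, with 2 CsA arrays. The matrix minus hepatocyte score moved with the agents there without overlap: it was -1.58 to -0.94 in untreated arrays, -0.75 and -0.68 with CsA and -0.81 to -0.64 with NIM811, and with it as a covariate, an alternative added later, 900 genes were called. A fit of the arrays compared alone gave 129, and leaving out 1 array gave 142 (control replicate 3) to 357 (control replicate 1).

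At 48 h in Huh7, CsA raised CSTA, an inhibitor of cysteine proteases, by 1.79 ± 0.40, ALDH1L2, a mitochondrial folate enzyme, by 1.75 ± 0.27, BHLHA15, a transcription factor of secretory cells, by 1.61 ± 0.34, and ERO1B, an oxidase of the ER, by 1.57 ± 0.41. PGLYRP2, a secreted liver amidase, fell by 1.25 ± 0.29 and EDNRB, an endothelin receptor, by 1.15 ± 0.24. In the ATF4 list 6 of 19 rose and none fell (15 adjusted over the list alone; adjusted p = 1.06e-16, but adjusted p = 0.056 with an estimated correlation). ASNS rose by 1.68 ± 0.43. The ER chaperone list had 5 of 16 higher (12 adjusted over the list alone; adjusted p = 8.45e-16, but adjusted p = 0.0635 with an estimated correlation). DNAJB9 rose by 1.39 ± 0.21. The ER to Golgi list had 5 of 19 higher, the same number adjusted over the list alone (adjusted p = 5.53e-09, and 0.0481 with an estimated correlation). Limma called 121 genes, 104 higher and 17 lower, and 111 of them were free of overlap, against 9.78% of all genes and 10% by chance. Control replicate 2 stood apart by the matrix minus hepatocyte score, at -0.50 against -1.83 and -1.49 in replicates 1 and 3. The 6 arrays compared, fitted alone, called 0 genes, and leaving out 1 array gave 47 (control replicate 1) to 202 (control replicate 3).

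NIM811 at 12 h in Huh7 also raised metallothioneins, MT1M by 3.90 ± 0.75, MT1E by 3.23 ± 0.68 and MT1X by 3.19 ± 0.64, and lowered SLC39A10 by -1.46 ± 0.37 and the linker histone gene H1-10 by -1.20 ± 0.26. Of the ER to Golgi genes 8 of 19 rose and none fell (15 adjusted over the list alone; adjusted p = 3.1e-22, and 9e-05 with an estimated correlation). SEC24D rose by 1.14 ± 0.24 and ARFGAP3 by 1.05 ± 0.17. Of the ER chaperone genes 5 of 16 rose (12 adjusted over the list alone; adjusted p = 1.49e-18, but adjusted p = 0.0877 with an estimated correlation). CRELD2 rose by 1.26 ± 0.18 and SDF2L1 by 1.22 ± 0.19. Limma called 134 genes, 108 higher and 26 lower, and 133 were free of overlap, against 22.1% of all genes and 10% by chance. Without 1 array the count lay between 62, without control replicate 2, and 129, without control replicate 1.

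At 24 h in Huh7, NIM811 raised the ATF4 list, 12 of 19 higher and none lower (18 adjusted over the list alone; adjusted p = 1.54e-33, and 0.00376 with an estimated correlation). DDIT4 rose by 2.42 ± 0.56, CHAC1 by 2.36 ± 0.48 and ASNS by 2.25 ± 0.43. Aminoacyl-tRNA synthetases had 6 of 14 higher (9 and 1 lower adjusted over the list alone; adjusted p = 3.38e-12, and 0.00429 with an estimated correlation). WARS1 rose by 1.39 ± 0.18. The mitosis list had a mean of -0.47 with 1 of 20 genes lower, TOP2A at -0.78 ± 0.17 (8 adjusted over the list alone; adjusted p = 2.84e-11, but adjusted p = 0.31 with an estimated correlation). MT1M rose by 3.44 ± 0.75, while EDNRB changed by -1.57 ± 0.24, FAM151A by -1.42 ± 0.36 and DGAT2 by -1.40 ± 0.29. Limma called 203 genes, 149 higher and 54 lower, and 505 with the matrix minus hepatocyte score, which moved as given for CsA, as a covariate. A fit of the arrays compared alone gave 126, and leaving out 1 array gave 80 (NIM811 replicate 3) to 143 (control replicate 1).

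At 48 h in Huh7, NIM811 raised CSTA by 1.95 ± 0.40, FBXO16, a subunit of ubiquitin ligases, 2.84-fold, BHLHA15 by 1.47 ± 0.34 and WARS1 by 1.29 ± 0.18. Haptoglobin (HP) was 5.49-fold lower, at -2.46 ± 0.41 (-1.84 and still called without NIM811 replicate 1), the adhesion molecule BCAM was at -1.29 ± 0.36 and HRG, a plasma glycoprotein made by liver, at -1.27 ± 0.23. In the ATF4 list 2 of 19 rose (4 adjusted over the list alone; mean 0.60, adjusted p = 1.63e-06, but adjusted p = 0.517 with an estimated correlation). In the ER to Golgi list 5 of 19 rose, the same number adjusted over the list alone (adjusted p = 1.9e-06, but adjusted p = 0.188 with an estimated correlation). ARFGAP3 rose by 1.13 ± 0.17. The lipoprotein list had a mean of -0.36 with 0 of 18 genes called by limma, also when adjusted over the list alone (adjusted p = 0.00474, but adjusted p = 0.652 with an estimated correlation). Limma called 230 genes, 144 higher and 86 lower, and 212 were free of overlap, against 13.4% of all genes and 10% by chance. Control replicate 2 stood apart from the other controls, as given for CsA at this time. Signs of RNA quality differed too. The log2 ratio of the GAPDH probe sets was at least 0.0557 in controls and at most -0.0085 with NIM811. The mean beta-actin ratio was 0.792 and 0.532. A fit of only the 6 arrays compared called 0 genes, and leaving out 1 array gave 36 (control replicate 1) to 677 (control replicate 2).

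In Clone A at 12 h, CsA raised MT1X 88.5-fold, by a log2 change of 6.47 ± 0.64, MT1E by 6.19 ± 0.68 and MT2A by 5.69 ± 0.53, all metallothioneins. MT1X had a mean log2 intensity of 6.27 in these untreated arrays and of 9.36 in untreated Huh7 at 12 h, and the untreated lines differed in it by -3.09 ± 0.64 at 12 h and by 3.02 ± 0.64 at 24 h. The pseudogene transcript GOLGA2P5 fell by 2.42 ± 0.28, ACTN3 by 2.31 ± 0.62 and the zinc importer SLC39A10 by 2.30 ± 0.37. The ER to Golgi list had 11 of 19 genes higher and none lower (14 adjusted over the list alone; adjusted p = 1.85e-08, and 0.0494 with an estimated correlation). ARFGAP3 rose by 1.90 ± 0.17 and SEC24D by 1.90 ± 0.24. Of 16 ER chaperone genes 9 rose (11 adjusted over the list alone; adjusted p = 8.53e-06, but adjusted p = 0.554 with an estimated correlation). DNAJB9 rose by 1.84 ± 0.21 and HERPUD1, which helps degrade misfolded proteins, by 1.33 ± 0.23. Genes of ribosome biogenesis had 9 of 12 higher (10 adjusted over the list alone; mean 0.41, adjusted p = 0.000762, but adjusted p = 0.554 with an estimated correlation). In the DNA replication list 9 of 21 fell and 2 rose, the same counts when adjusted over the list alone: CDC6, which loads replication helicases, rose by 1.31 ± 0.19, while the helicase subunits MCM4 and MCM5 changed by -0.82 ± 0.18 and -0.80 ± 0.20 (adjusted p = 0.00245, but adjusted p = 0.647 with an estimated correlation). The hepatocyte function list had 3 of 15 genes lower, as when adjusted over the list alone, led by the asialoglycoprotein receptor ASGR1 at -1.42 ± 0.46 (adjusted p = 0.00301, but adjusted p = 0.647 with an estimated correlation).

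Limma called 3007 genes for CsA in Clone A at 12 h, 1824 higher and 1183 lower, and 2721 of them were free of overlap, against 35.5% of all genes and 10% by chance. With median centring the split was 2146 higher and 890 lower, and with quantile normalization 1660 and 1417. A score of matrix genes minus hepatocyte genes moved with the agent there: it was -1.58 ± 0.07 (SD) in the untreated Clone A arrays at 12 h, -0.54 ± 0.63 with CsA and -0.62 ± 0.78 with NIM811, and in untreated Clone A -0.62 ± 0.04 at 24 h and -0.86 ± 1.12 at 48 h (-1.53, -1.48 and 0.43 by replicate). The log2 ratio of the beta-actin probe sets, a sign of RNA quality, was at least 0.801 in the untreated arrays (mean 0.936) and at most 0.550 with CsA (mean 0.489), and with it as a covariate, an alternative added later, limma called 1770 genes. The untreated Clone A arrays at 12 h also differed in 2671 genes from the mean of those at 24 and 48 h, a comparison that called 0 genes in untreated Huh7 by limma; they differed in 2518 from those at 24 h and in 670 from those at 48 h, which differed from each other in 10. Fitted alone, the 6 arrays compared gave 1487 genes, and leaving out 1 array gave 1704 (control replicate 3) to 3611 (CsA replicate 2).

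At 24 h in Clone A, CsA lowered genes of the cell cycle. All 20 mitosis genes fell, also when adjusted over the list alone, with a mean of -1.54: the spindle motor KIF11 changed by -1.91 ± 0.28, KIF20A by -1.82 ± 0.26, the proliferation marker MKI67 by -1.81 ± 0.30 and the checkpoint kinase BUB1 by -1.77 ± 0.25 (adjusted p = 5.83e-50, and 0.00265 with an estimated correlation). Of the DNA replication genes 16 of 21 fell and none rose (20 adjusted over the list alone; adjusted p = 1.05e-19, and 0.0461 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, changed by -1.83 ± 0.24 and TYMS, thymidylate synthase, by -1.21 ± 0.22. The ATF4 list had 10 of 19 higher (18 adjusted over the list alone; adjusted p = 2.51e-17, and 0.0336 with an estimated correlation). DDIT4 rose by 2.09 ± 0.56. The ER chaperone list had 11 of 16 higher (14 adjusted over the list alone; adjusted p = 1.61e-16, and 0.0483 with an estimated correlation). DNAJB9 rose by 1.37 ± 0.21. The largest single rises were CTHRC1, a secreted collagen-related protein, at 2.40 ± 0.69 and FIBIN, a secreted protein, at 2.17 ± 0.36. The largest falls were ID4, an inhibitor of transcription factors, at -2.42 ± 0.46 and HAMP, the iron hormone hepcidin, at -2.37 ± 0.42. By the matrix minus hepatocyte score CsA replicate 1 stood apart, at 0.06 against -0.94 and -0.88, with -0.65 to -0.57 in untreated arrays. Limma called 832 genes, 328 higher and 504 lower. A fit of only the arrays compared gave 2208, and leaving out 1 array gave 485 (CsA replicate 1) to 696 (CsA replicate 2).

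At 48 h in Clone A, CsA raised NUCB2, a calcium-binding precursor of nesfatin, by 1.94 ± 0.36, CSTA by 1.90 ± 0.40, the transporter SLC17A2 by 1.70 ± 0.44 and FICD, an ER enzyme that modifies the chaperone HSPA5, by 1.66 ± 0.37. AGXT2, a mitochondrial aminotransferase, fell by 1.36 ± 0.34, HMOX1, heme oxygenase, by 1.26 ± 0.26 and DGAT2 by 1.19 ± 0.29. Of 16 ER chaperone genes 9 rose and none fell (15 adjusted over the list alone; adjusted p = 4.16e-28, and 0.00829 with an estimated correlation). DNAJB9 rose by 1.53 ± 0.21 and CRELD2 by 1.08 ± 0.18. Of 19 ER to Golgi genes 5 rose (9 adjusted over the list alone; adjusted p = 1.14e-13, and 0.00243 with an estimated correlation). The mitosis list had a mean of -0.45 with 0 of 20 genes called by limma (5 lower adjusted over the list alone; adjusted p = 2.53e-11, but adjusted p = 0.313 with an estimated correlation). Limma called 125 genes, 96 higher and 29 lower, and 122 were free of overlap, against 10.3% of all genes and 10% by chance. The 6 arrays compared, fitted alone, called 0 genes, and leaving out 1 array gave 46 (CsA replicate 1) to 325 (CsA replicate 3). The 3 pairs of control and CsA arrays with the same number had residual correlations of 0.653 to 0.848, and with the numbers as blocks limma called 235 genes. Replicate 3 stood apart in both groups by the matrix minus hepatocyte score, at 0.43 in controls and 0.02 with CsA. The other arrays were at -1.36 or lower.

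NIM811 at 12 h in Clone A raised MT1X 102-fold, by 6.67 ± 0.64, MT1E by 6.37 ± 0.68 and MT2A by 5.86 ± 0.53. SLC39A10 changed by -2.43 ± 0.37, GOLGA2P5 by -2.43 ± 0.28 and the methyltransferase-like TMT1A by -2.20 ± 0.62. The ER to Golgi list had 12 of 19 higher and none lower (15 adjusted over the list alone; adjusted p = 2.29e-06, but adjusted p = 0.164 with an estimated correlation). SEC24D rose by 2.14 ± 0.24 and ARFGAP3 by 2.01 ± 0.17. The lipoprotein and lipid trafficking list had 9 of 18 genes lower and 1 higher (10 and 1 adjusted over the list alone; mean -0.68, adjusted p = 0.00145, but adjusted p = 0.651 with an estimated correlation). The ER chaperone list had 7 of 16 higher (9 adjusted over the list alone; adjusted p = 0.0073, but adjusted p = 0.651 with an estimated correlation). DNAJB9 rose by 1.74 ± 0.21. Limma called 4109 genes, 2750 higher and 1359 lower, beside the shifts of the score and of the untreated arrays given for CsA at this time. The split depended on scaling: it was 3390 higher and 920 lower with median centring, and 2327 and 1622 with quantile normalization. NIM811 replicate 1 had log2 ratios of 0.656 for the GAPDH and 1.47 for the beta-actin probe sets, signs of RNA quality, against -0.0315 and 0.391 in replicate 2 and -0.0186 and 0.463 in replicate 3. With the score as a covariate, an alternative added later, 2699 genes were called. Leaving out 1 array gave 2556 (control replicate 3) to 4083 (NIM811 replicate 1).

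At 24 h in Clone A, NIM811 lowered 18 of 20 mitosis genes and raised none (20 adjusted over the list alone), with a mean of -1.17 (adjusted p = 6.43e-38, and 0.00723 with an estimated correlation). TOP2A changed by -1.59 ± 0.17, KIF11 by -1.56 ± 0.28 and MKI67 by -1.45 ± 0.30. Of the DNA replication genes 5 of 21 fell (14, and 1 higher, adjusted over the list alone; adjusted p = 1.52e-09, but adjusted p = 0.29 with an estimated correlation). RRM2 changed by -1.24 ± 0.24. Of 16 ER chaperone genes 12 rose (14 adjusted over the list alone; adjusted p = 7.23e-18, and 0.0421 with an estimated correlation). HERPUD1 rose by 1.41 ± 0.23 and DNAJB9 by 1.39 ± 0.21. The ATF4 list had 10 of 19 higher (18 adjusted over the list alone; adjusted p = 5.65e-19, and 0.0218 with an estimated correlation). DDIT4 rose by 2.15 ± 0.56. FIBIN rose by 2.52 ± 0.36, CTHRC1 by 2.43 ± 0.69 and FICD by 2.17 ± 0.37, and DGAT2 changed by -1.99 ± 0.29. Limma called 635 genes, 325 higher and 310 lower. A fit of only the arrays compared gave 2953, and leaving out 1 array gave 326 (control replicate 3) to 435 (NIM811 replicate 2).

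At 48 h in Clone A, NIM811 raised ZBTB8A, a zinc finger protein, by 1.66 ± 0.21, BHLHA15 by 1.66 ± 0.34, WARS1 by 1.64 ± 0.18 and BCAT1, which starts the breakdown of branched amino acids, by 1.56 ± 0.19. HP fell by 1.85 ± 0.41 (not called without control replicate 1 or 2 or without NIM811 replicate 2 or 3), AGXT2 by 1.62 ± 0.34, DGAT2 by 1.55 ± 0.29 and SLPI, a secreted protease inhibitor, by 1.34 ± 0.32. Of 19 ER to Golgi genes 6 rose and none fell (11 adjusted over the list alone; adjusted p = 7.99e-12, and 0.00668 with an estimated correlation). SEC24D rose by 1.21 ± 0.24. Aminoacyl-tRNA synthetases had 5 of 14 higher (11 adjusted over the list alone; adjusted p = 2.59e-11, and 0.00668 with an estimated correlation). The lipoprotein list had a mean of -0.55 with 1 of 18 lower, as when adjusted over the list alone (adjusted p = 5.81e-05, but adjusted p = 0.507 with an estimated correlation), and the cholesterol synthesis list a mean of -0.36 with 0 of 18 called by limma, also over the list alone (adjusted p = 0.000416, but adjusted p = 0.507 with an estimated correlation). The matrix minus hepatocyte score was -0.86 ± 1.12 (SD) in the untreated arrays of this comparison and -0.14 ± 1.02 with NIM811. By replicate it was -1.53, -1.48 and 0.43 in untreated arrays and -1.32, 0.47 and 0.43 with NIM811, so arrays stood apart within each group. The falls of HP and of the lipoprotein and cholesterol lists may hold this shift as well as the agent. Limma called 243 genes, 149 higher and 94 lower, and 193 were free of overlap, against 14.4% of all genes and 10% by chance. The 6 arrays compared, fitted alone, called 0 genes, and leaving out 1 array gave 59 (control replicate 1) to 1343 (control replicate 3).

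**Figure D1:**
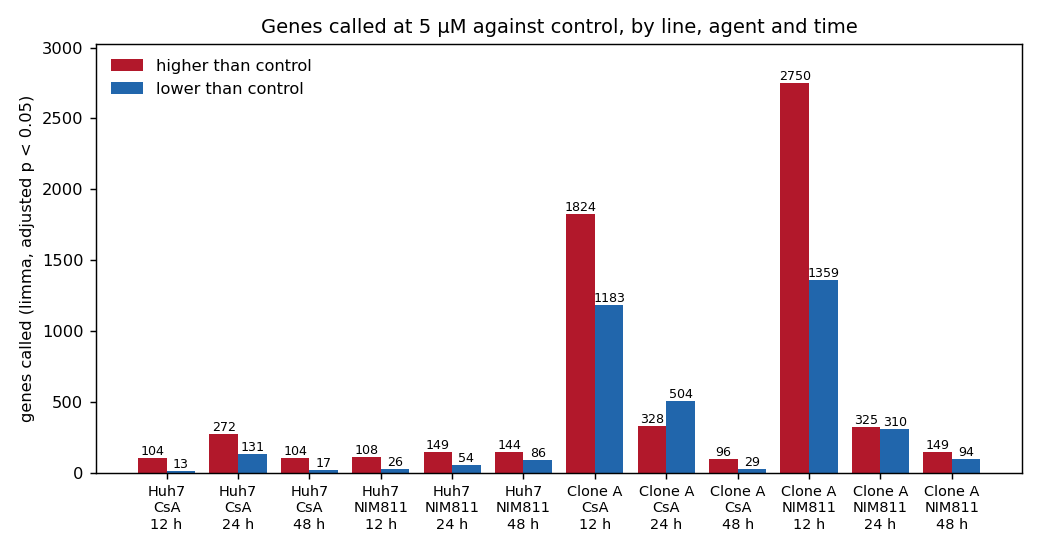
Bars show the number of genes called higher (red) or lower (blue) than control by limma at an adjusted p under 0.05, on a linear axis from 0, for each line, agent and time at 5 µM. The counts run from 117 genes for CsA in Huh7 at 12 h to 4109 for NIM811 in Clone A at 12 h.

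**Figure D2:**
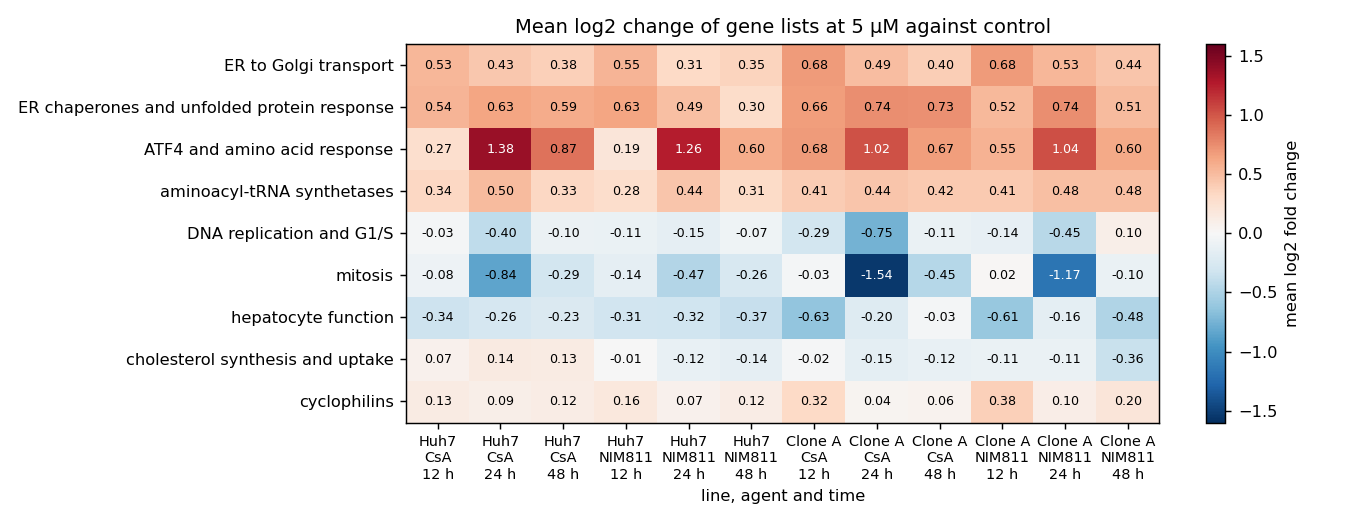
Each cell gives the mean log2 fold change against control over the tested members of a gene list (vertical axis) for a line, agent and time at 5 µM (horizontal axis), coloured from blue (lower) to red (higher). The ER to Golgi and ER chaperone lists are above 0 in all 12 columns, and mitosis is lowest at 24 h, at -1.54 and -1.17 in Clone A.

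A small core of genes was called higher in all 12 comparisons of an agent at 5 µM with control. It held 24 genes, picked here for this and not by the rule for named genes, and included ARFGAP3, DNAJB9, the ER translocon subunit SEC61B, the vesicle coat subunit SEC23B, WARS1 and EIF4EBP1, a brake on translation. DGAT2 was called lower in 10 of the 12 comparisons, and so was LAMC1, a laminin chain. At 12 h 79 genes were higher and 7 lower in all 4 comparisons of that time, at 24 h 91 and 20, and at 48 h 40 and 2. The comparisons of a line and time share their controls, which adds to such counts.

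**Figure D3:**
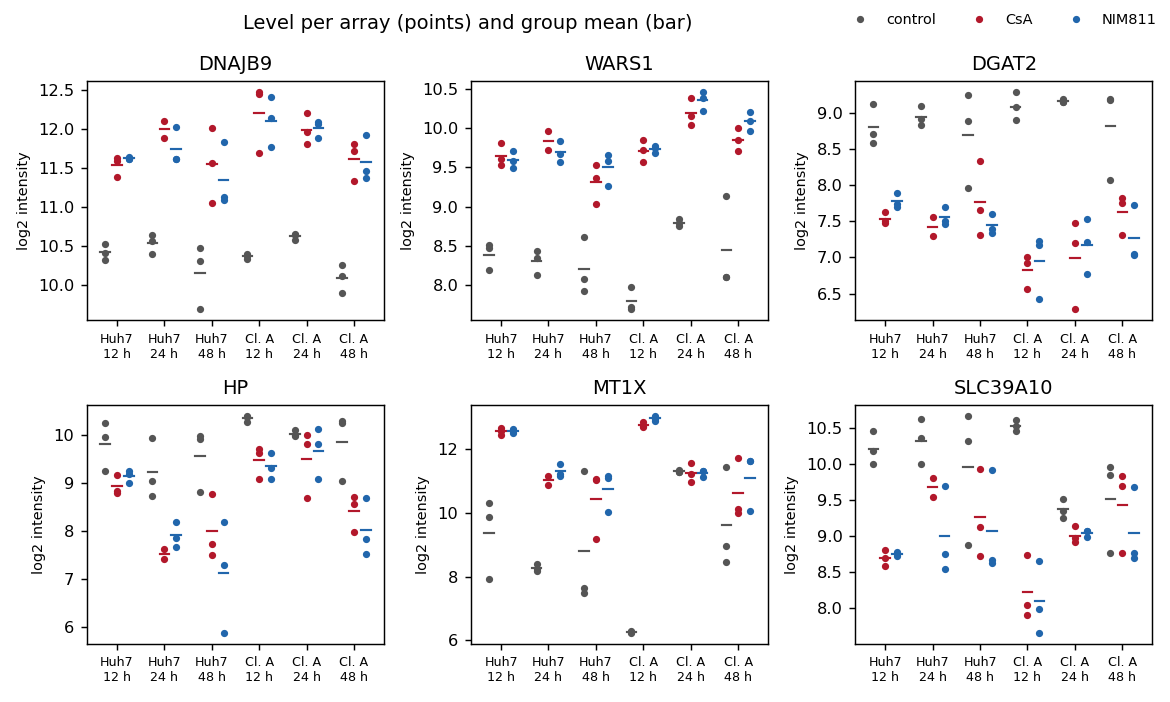
Points are log2 intensities of single arrays of the first set and bars are group means, for 6 genes, by line and time on the horizontal axis and by agent in colour (control grey, CsA red, NIM811 blue). DNAJB9 and WARS1 lie above control in all 6 line and time groups, while MT1X in untreated Clone A is near 6.27 at 12 h and far higher later.

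Some genes were chosen in advance for what these agents bind or act on. DDIT3, a transcription factor of the ER stress and amino acid responses, was not called in Huh7 at 12 h and rose there at 24 h by 0.88 ± 0.16 with CsA and 0.79 ± 0.15 with NIM811, and at 48 h by 0.92 ± 0.15 and 0.70 ± 0.15. In Clone A it rose at 12 h by 0.71 ± 0.15 and 0.58 ± 0.15 and at 24 h by 0.65 ± 0.15 and 0.69 ± 0.15, and was not called at 48 h (0.48 ± 0.15 and 0.45 ± 0.15). In untreated cells it was higher in Clone A by 0.68 ± 0.08. HSPA5, the main ER chaperone, was called in Clone A with both agents at all 3 times, by 0.39 ± 0.12 to 0.53 ± 0.12, and in Huh7 in none of 6 comparisons, where limma gave 0.11 ± 0.12 to 0.34 ± 0.12; the mean difference between lines was 0.21 with CsA (adjusted p = 0.910) and 0.24 with NIM811 (adjusted p = 0.558). PPIA, the most abundant cyclophilin, rose in Clone A at 12 h by 0.21 ± 0.08 with CsA and by 0.26 ± 0.08 with NIM811, and PPIF, the mitochondrial cyclophilin, by 0.80 ± 0.17 and 0.95 ± 0.17. The cyclophilin list had 6 of 16 genes higher there with CsA (adjusted p = 0.0202, but adjusted p = 0.554 with an estimated correlation) and 8 with NIM811 (adjusted p = 0.0276, but adjusted p = 0.651 with an estimated correlation), the same counts when adjusted over the list alone. Of all 13196 genes, 1824 were called higher by limma with CsA and 2750 with NIM811 in Clone A at 12 h. The untreated arrays there differed in 2671 genes from the later ones, so the rises of cyclophilins may hold that shift as well as the agents. PPIB, the cyclophilin of the ER, was not called for either agent, and was lower in untreated Clone A than in Huh7 by -0.35 ± 0.10. RCAN1, a target of calcineurin signalling, lay between -0.36 and 0.79 in the 12 comparisons and HMGCS1, a cholesterol synthesis gene, between -0.22 and 0.27, and limma called neither. These are 7 of the 8 genes named in advance, and the remaining gene was not among those tested.

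At the same dose and time, no gene was called between CsA and NIM811 by limma in either line. The counts at an unadjusted p under 0.05 were 87, 698 and 248 in Huh7 at 12, 24 and 48 h and 460, 241 and 963 in Clone A, and the lowest adjusted p was 0.0509, in Clone A at 12 h. Chance alone would give a share of 0.05 of the 13196 genes, and only the counts of 698 and 963 exceed it. The test may thus be too strict here, so the absence of calls does not show equal effects of the agents. The 95% interval of the difference lay within 2-fold for 97.7%, 90.2% and 94.9% of genes in Huh7 and for 96.7%, 96.6% and 91.6% in Clone A, with a median distance from the estimate to each limit of 0.35 on the log2 scale, or 0.40 in Huh7 at 24 h. The estimated difference itself exceeded 2-fold for 75 genes in Huh7 at 24 h, 11 in Huh7 at 48 h and 42 in Clone A at 48 h, and for 0 genes elsewhere by limma. Leaving out 1 array called 23 genes in Huh7 at 24 h (without CsA replicate 2), 25 in Clone A at 12 h (without CsA replicate 3) and 327 in Clone A at 48 h (without CsA replicate 3).

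Several lists differed in their mean between the agents, although limma called none of their members. Mitosis genes were lower with CsA than with NIM811 at 24 h by a mean of -0.37 in Huh7 (adjusted p = 8.07e-11, but adjusted p = 0.471 with an estimated correlation) and of -0.37 in Clone A (adjusted p = 1.92e-14, but adjusted p = 0.266 with an estimated correlation), with 1 gene called in each when adjusted over the list alone. ER chaperones were higher with CsA in Huh7 at 48 h by 0.29 (adjusted p = 6.24e-10, but adjusted p = 0.552 with an estimated correlation). Lipoprotein genes were higher with CsA than with NIM811 in Clone A at 48 h by 0.55 (adjusted p = 1.3e-06, but adjusted p = 0.61 with an estimated correlation). The matrix minus hepatocyte score differed there too, with means of -0.94 and -0.14, and with it as a covariate the mean of lipoproteins and lipid trafficking was 0.13 (adjusted p = 0.0590). RCAN1, which calcineurin activity induces, differed between CsA and NIM811 by -0.50 in Huh7 at 48 h (95% interval -1.34 to 0.35) and by -0.73 in Clone A at 48 h (-1.57 to 0.12).

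The changes with CsA and with NIM811 went together across genes, which are not independent replicates: r was 0.888, 0.688 and 0.785 in Huh7 at 12, 24 and 48 h and 0.948, 0.886 and 0.571 in Clone A. Both changes are taken from the same control arrays, and simulated data with no effect gave r of 0.445 in Huh7 at 24 h and of 0.499 to 0.501 otherwise, with a covariance of 0.0225 in Huh7 at 12 h. The covariance exceeded the simulated value by 0.0351, 0.0425 and 0.0369 in Huh7 and by 0.222, 0.0718 and 0.0208 in Clone A. The simulation drew independent noise for each group, with the same spread of a gene in all groups. The real CsA and NIM811 arrays with the same number had residual correlations of 0.467 to 0.787 in Clone A at 12 h. Untreated Clone A arrays at 48 h also varied widely, with an SD of 1.12 in the matrix minus hepatocyte score. The excess may therefore hold states of the arrays as well as the agents. Genes called with both agents numbered 82 higher and 7 lower in Huh7 at 12 h, where independent calls would give 0.851 and 0.0256, then 126 and 28 at 24 h (3.07 and 0.536) and 73 and 11 at 48 h (1.13 and 0.111). In Clone A they numbered 1706 and 882 at 12 h (380.1 and 121.8), 240 and 262 at 24 h (8.08 and 11.8) and 66 and 17 at 48 h (1.08 and 0.207). Part of the excess may come from the shared controls.

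**Figure D4:**
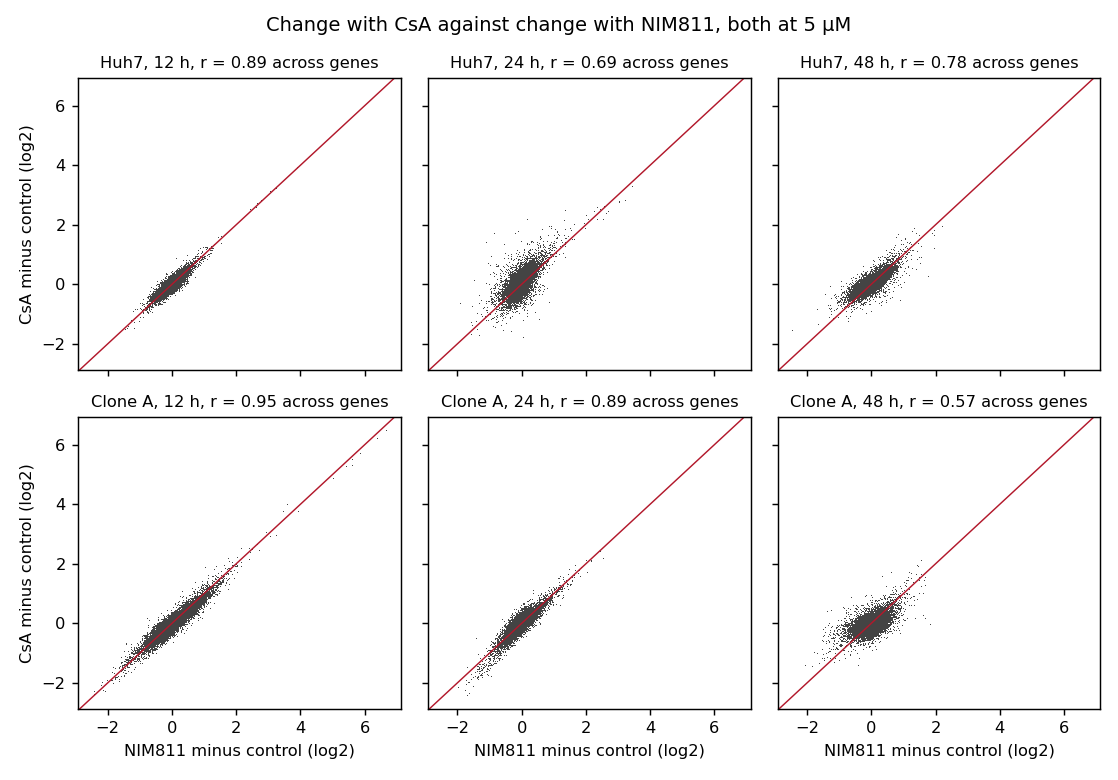
Each point is a gene, at its log2 change with NIM811 against control (horizontal axis) and with CsA against control (vertical axis), both at 5 µM, in 6 panels by line and time; the red line marks equal change. The correlation across genes was highest in Clone A at 12 h (r = 0.948) and lowest in Clone A at 48 h (r = 0.571), and the median absolute difference was smallest in Huh7 at 12 h, at 0.08.

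Whether the replicon line responded differently was tested as the difference of the responses between the lines. Averaged over the 3 times, 10 genes differed with CsA, 3 higher and 7 lower in Clone A. HEY1, a transcription factor downstream of Notch, differed by 0.98 ± 0.15, LIF, a cytokine, by 0.73 ± 0.14 and TRIM44 by 0.60 ± 0.13, while SPC24, a kinetochore subunit, differed by -0.91 ± 0.14, C1orf174 by -0.79 ± 0.14 and CYB561, a cytochrome of transmembrane electron transfer, by -0.73 ± 0.14. With NIM811 3 genes differed: HEY1 by 0.83 ± 0.15, CYB561 by -0.71 ± 0.14 and SPC24 by -0.68 ± 0.14. The count with NIM811 ran from 0, by limma, to 41 when 1 array was left out, and was 1 with trend and robust moderation and 36 with replicate blocks. Over 24 and 48 h alone, an alternative added later, the counts were 4 and 0, the latter by limma with 0 higher and 0 lower.

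At each time, tested as an addition, the difference of responses called 32 genes with CsA at 12 h, 1 at 24 h and 0 at 48 h (353 at an unadjusted p under 0.05 by limma), and with NIM811 372 genes at 12 h, 0 at 24 h (329 at an unadjusted p under 0.05) and 0 at 48 h (454). These unadjusted counts lie below the share of 0.05 of genes that chance alone would give, so they do not show equal responses. At 12 h the largest differences with CsA were NNMT, a methyltransferase of nicotinamide, at 3.42 ± 0.75, CYP1B1, a cytochrome P450, at 3.26 ± 0.76 and the scaffold protein AKAP12 at 2.76 ± 0.56, and with NIM811 MT1X at 3.48 ± 0.91, MT2A at 3.43 ± 0.76 and NNMT at 3.33 ± 0.75. The 1 gene with CsA at 24 h was SPC24 at -1.40 ± 0.25. The mitosis list differed at 24 h by a mean of -0.70 with CsA (adjusted p = 1.95e-15, but adjusted p = 0.607 with an estimated correlation; 4 genes lower adjusted over the list alone) and of -0.70 with NIM811 (adjusted p = 8.11e-27, but adjusted p = 0.0818 with an estimated correlation; 12 lower adjusted over the list alone). Genes called with an agent in both lines numbered 110, 225 and 55 with CsA at 12, 24 and 48 h and 108, 140 and 86 with NIM811, and 0 of these moved in opposite directions by limma. Leaving out 1 array gave 6 (untreated Clone A replicate 3) to 71 (Clone A CsA replicate 3) with CsA at 12 h, and 61 (Huh7 NIM811 replicate 3) to 479 (untreated Huh7 replicate 1) with NIM811.

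The second set asked what a 1 µM dose did, and is given as counts over 20844 rows without gene names. In Huh7 at 48 h limma called 0 rows for CsA 1 µM (65 at an unadjusted p under 0.05) and 0 for NIM811 1 µM (103), and 0 in Clone A for NIM811 1 µM (713). Chance alone would give a share of 0.05 of the rows, and these unadjusted counts lie below it, as do those at 5 µM in Huh7. The test may thus be too strict, so the absence of calls does not show the absence of an effect. At 5 µM limma called 0 rows for CsA (227) and 0 for NIM811 (631) in Huh7, and 366 for NIM811 in Clone A, 339 higher and 27 lower. The latter became 198 and 72 with median centring, 261 and 90 with quantile normalization, 89 rows with only the arrays compared and 0 by limma with each line fitted alone. That count rose with replicate numbers as blocks, as given further below, though pairing was not shown for these arrays. The 1 µM arrays share no replicate number with the others, so their comparisons with control and with 5 µM rest on the unpaired fit. Replicate numbers paired the Huh7 arrays of this set: all 9 pairs of arrays with the same number had correlated residuals, of 0.531 to 0.795, and with the numbers as blocks NIM811 5 µM called 238 rows in Huh7. Untreated Clone A and Huh7 differed in 5634 rows, 2773 higher and 2861 lower, and in 3303 with the numbers as blocks.

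Between doses limma called 0 rows for CsA in Huh7 at 48 h (270 at an unadjusted p under 0.05), 0 for NIM811 in Huh7 at 48 h (464), 0 for CsA in Clone A at 24 h (1783, lowest adjusted p 0.0502) and 0 for NIM811 in Clone A at 48 h (1407). CsA 1 µM against NIM811 1 µM in Huh7 gave 0 rows (53), also with the numbers as blocks, and CsA 5 µM against NIM811 5 µM 0 rows (85). The unadjusted counts in Huh7 here again lie below a share of 0.05 of the rows, so they do not show equal effects. The 339 rows raised by NIM811 5 µM in Clone A had a median log2 change of 0.95 at 5 µM and of 0.40 at 1 µM, where simulated data with no effect of the low dose, sharing the controls, gave 0.08. The 27 lowered rows had medians of -0.72 and -0.22, against -0.10 in the simulation. The simulation took the observed 5 µM changes as true, which understates what noise of the shared controls adds to rows chosen by their call. The gap between real and simulated values therefore does not show an effect of 1 µM. Clone A with CsA at 24 h had no untreated arrays of its own time in this set, so it was set against those of 48 h: 0 rows were called for 1 µM by limma (137 at an unadjusted p under 0.05) and 7, all higher, for 5 µM (1893), and these values hold the time as well as the agent. Leaving out 1 array gave 0 (without NIM811 replicate 4) to 509 (without control replicate 4) rows for NIM811 5 µM in Clone A, and 0 (without control replicate 4) to 863 (without CsA replicate 4) for CsA 5 µM at 24 h in Clone A.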

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

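The tests of row order and of array quality in the second set and of RNA degradation with CsA were chosen only after the result was seen, as were the pairs of untreated times, the covariates and the interactions at each time. A difference of the response between the lines was found for 10 genes with CsA and for 3 with NIM811 over the mean of the times. Of 100 splits of the arrays, the real one counted here and below, 3 gave as many genes for CsA, with 276 as the highest other count, and 7 for NIM811, with 874. The splits exchanged treated and untreated arrays within each line and time, so they stand for no drug effect and not for an equal response. They therefore cannot decide whether chance gave the difference between the lines. At 12 h the response differed for 32 genes with CsA and for 372 with NIM811. Of 100 such splits, 15 and 13 gave as many, with highest other counts of 1719 and 2279. For the same reason this cannot decide whether chance gave either count. At 24 h it differed for 1 gene with CsA. At 48 h with CsA, and at 24 and 48 h with NIM811, limma called 0 genes (353, 329 and 454 at an unadjusted p under 0.05), and all 100 splits gave as many, as any split must, with highest other counts of 3290, 247 and 3859. Some splits carry the drug effect itself into the difference between the lines. Counts several times the real one therefore do not by themselves point to a structure of the samples.

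The agents called many more genes in Clone A than in Huh7 at 12 h. The untreated Clone A arrays at 12 h differed in 2671 genes from those of 24 and 48 h, against 532 genes for the CsA arrays and 335 for the NIM811 arrays of Clone A; in Huh7 limma called 0, 28 and 19. This is what controls standing apart at 12 h would give, so part of the count may come from the state of those controls, though by the matrix minus hepatocyte score (mean -1.58) they lie apart from those at 24 h (-0.62) and near replicates 1 and 2 at 48 h (-1.53 and -1.48). With the ratio of beta-actin probe sets as a covariate limma called 1770 genes for CsA (1589 of the 3007), which leaves RNA degradation open. For NIM811 it called 3922 (3782 of the 4109), a count kept as it would be without degradation, but this cannot decide. NIM811 replicate 1 had a ratio of 1.47, against 0.391 and 0.463 in the others. It brought the mean to 0.774, near the 0.936 of controls, so the covariate had little group difference to remove. With the score limma called 2699 for NIM811 (2332 of the 4109), which does not tell the explanations apart. A larger response of the replicon line could also raise the count: the slope of the Clone A change on the Huh7 change was 1.44 (95% interval 1.21 to 1.62) over 134 genes but 1.04 over 126 genes without metallothioneins. The interval comes from resampling genes, which share the same arrays, so it measures the spread over genes and not between arrays.

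The rows of the second set do not follow those of the first. Rows were matched by level and line difference of the untreated arrays at 48 h, with the treated arrays left out. The drug effects then had correlations between the sets of 0.408 and 0.311 for NIM811 and CsA in Huh7 and of 0.536 for NIM811 in Clone A. The same match to reversed rows gave at most 0.0225, and the rows as listed -0.000472, 0.00402 and -0.000801. The untreated arrays used for the match are also part of each drug effect, so the match itself can add to these correlations. The reversed match is a weak check, since its levels had a correlation of 0.181, against 0.929. Values listed against the wrong rows would give this, and are the explanation taken here for reporting the second set without gene names. Other values, which do not rest on the match, go with it. The values of the second set filled the first 20844 rows without a gap. Between 2 probe sets of a gene the line difference had a correlation of 0.0339 there, against 0.650 in the first set. Low array quality is argued against by the 5634 rows that differ between the lines within the second set.

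Metallothioneins rose at 12 h while the zinc importer SLC39A10 fell. More metal in the treated cultures may account for this: the zinc exporter SLC30A1, named outside the rule, was higher in 4 of 4 comparisons at 12 h, by 0.92 ± 0.21 and 1.14 ± 0.21 in Huh7 and 1.94 ± 0.21 and 1.86 ± 0.21 in Clone A with CsA and NIM811. Probe sets of the family could also read 1 transcript through cross-hybridisation, and the lowest residual correlation between them was 0.896, which does not tell whether they do. In Clone A at 24 h neither rise was called, with MT1X at -0.06 and -0.04 and SLC30A1 at 0.21 and 0.11 with CsA and NIM811. The untreated lines also differed in MT1X, by -3.09 ± 0.64 at 12 h and 3.02 ± 0.64 at 24 h. Single untreated arrays at 48 h stood high as well. MT1X was at 11.29 in Huh7 control replicate 2, against 7.65 and 7.48 in replicates 1 and 3. In Clone A it was at 11.43 in control replicate 3, against 8.45 and 8.94 in replicates 1 and 2. SLC39A10 was at 8.87 and 8.76 in those high arrays. High MT1X with low SLC39A10 thus also occurred without an agent, which metal in treated cultures alone would not explain.

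For the untreated lines over the mean of the times, 1 of 100 splits, the real one, gave 6422 genes, the highest other giving 3690, so chance regrouping is excluded at 0.05. For 3 arrays against 3 the 10 splits are too few for a share under 0.05, and the real count and the highest other are given. The real split alone, 1 of 10, gave as many genes for the lines at 12 h (4549, highest other 0), 24 h (2186, 0) and 48 h (2967, 1158). The same held for CsA in Huh7 at 12 h (117, 0), for NIM811 in Huh7 at 12 h (134, 0) and 24 h (203, 86), for CsA in Clone A at 12 h (3007, 1) and 24 h (832, 0), for NIM811 in Clone A at 12 h (4109, 2) and 24 h (635, 0), and for the lines in the second set (5634, 4). At 48 h, with the real split among them, 3 of 10 gave as many for CsA in Huh7 (121, highest other 318), 2 for NIM811 in Huh7 (230, 1265), 4 for CsA in Clone A (125, 934) and 2 for NIM811 in Clone A (243, 4097). These larger counts point to a structure of the 48 h samples apart from the agents. For CsA in Clone A the splits did not keep the pairs of arrays with the same number, whose residuals were correlated.

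For CsA against NIM811, where limma called 0 genes, all 10 splits gave as many, as any split must, so only the highest other count informs; none were run in Huh7 at 24 h, with 2 CsA arrays. The highest other counts were 0 in Huh7 at 12 h and 1154 at 48 h, and 1980, 2 and 4756 in Clone A at 12, 24 and 48 h, the large ones again pointing to a structure of the samples. In the second set limma called 0 rows for CsA 1 µM, NIM811 1 µM, CsA 5 µM and NIM811 5 µM in Huh7, for both agents against each other at 1 and 5 µM, for both dose steps in Huh7, for NIM811 1 µM in Clone A and for CsA 1 µM at 24 h in Clone A. All 10 splits gave as many in each of these, with a highest other count of 0 by limma. For the dose step of CsA in Clone A at 24 h limma also called 0 rows, all 10 splits gave as many and the highest other was 125. For CsA 5 µM at 24 h in Clone A, against the 48 h control, 3 of 10 splits, the real one among them, gave as many as the 7 rows called, with a highest other count of 60.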

How the results depend on the processing

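Array weights, both covariates, the mean of 24 and 48 h, the interactions at each time, the dim filter of the second set and the block at 1 µM were chosen only after the results were seen. For the genes and lists the text names, a fit of only the arrays compared kept 292 of 398 genes on their side of the threshold and weakened 102, and an estimated correlation kept 27 of 218 list calls. Quantile normalization kept 388 genes, trend and robust moderation 389, blocks 388, and the mean of probe sets 363 of 393. The score covariate weakened 55 of 218 list calls and reversed 3, the actin ratio weakened 31, and the mean of 24 and 48 h weakened 6 of 14. With 1 array left out, 439 of 3691 gene rows and 295 of 1827 list rows were weaker and 6 list rows reversed. Array weights did not converge (weights 6.09e-18 to 9.99) and called 7727 genes for NIM811 in Clone A at 48 h and 7152 for CsA against NIM811 there, values not used. Fits across the sets, without the set term or with controls of 1 set, were not run, since the rows do not match. No group of a set had 4 arrays, so none was tested for a sample far from the others. The number of arrays limits precision. The cause was not tested for the changes below, unless the alternative has fewer arrays or counts other rows.

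With only the arrays compared, the lines differed in 3332 genes at 24 h and 319 at 48 h. CsA in Huh7 called 129 at 24 h and 0 at 48 h, NIM811 126 and 0; in Clone A CsA called 1487, 2208 and 0 at 12, 24 and 48 h and NIM811 2953 and 0 at 24 and 48 h, all by limma. The interaction with CsA gave 6 (mean), 50 (12 h) and 11 (24 h), that with NIM811 710 (12 h) and 22 (24 h). In the second set, CsA 5 µM at 24 h in Clone A gave 0 and NIM811 5 µM in Clone A 89. With each line alone these gave 0 and 0, and NIM811 5 µM in Huh7 gave 8.

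With no dim filter, CsA against NIM811 in Clone A at 12 h gave 1 and the mean NIM811 interaction 1; with a stricter filter 1 and 6. The latter gave 8 with median centring, 9 with quantile normalization, 12 with the mean of probe sets and 1 with trend and robust moderation. Quantile normalization gave 53 for the CsA interaction at 12 h and 1 for the CsA dose step in Clone A. The mean of probe sets gave 6 for the mean CsA interaction, 0 for that at 24 h and 239 for NIM811 at 12 h. Trend and robust moderation gave 23 for CsA 5 µM at 24 h in Clone A, second set. Counting all probe sets, the lines differed in 13504 (mean), 8967, 3751 and 5844; CsA in Huh7 gave 215, 623 and 202, NIM811 in Huh7 247 (12 h) and 349 (48 h), CsA in Clone A 5866 and 1390 (12, 24 h), NIM811 8289 and 1025, and the CsA interaction at 24 h 0.

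With replicate blocks, the lines differed in 1297 genes at 24 h and 1862 at 48 h. CsA in Huh7 gave 182 (12 h) and 215 (48 h), NIM811 358 (24 h) and 523 (48 h), CsA in Clone A 235 (48 h), NIM811 990 (24 h) and 658 (48 h). Interactions gave 36 (NIM811 mean), 154 and 3 (CsA 12, 24 h) and 988 (NIM811 12 h). In the second set NIM811 5 µM gave 238 in Huh7 and 2754 in Clone A, and the lines 3303; CsA against NIM811 at 1 µM in Huh7 stayed at 0 by limma. The score covariate gave 235, 900 and 321 for CsA and 265, 505 and 490 for NIM811 in Huh7, 1436 and 288 for CsA in Clone A at 24 and 48 h, 2699 and 1157 for NIM811 at 12 and 24 h, 1 for CsA against NIM811 in Clone A at 12 h, and 32, 75 and 6 for the interactions of NIM811 (mean) and CsA (12, 24 h). The actin ratio gave 631 and 309 for CsA and NIM811 in Huh7 at 24 h, 1770 for CsA in Clone A at 12 h, 394 for NIM811 at 48 h, and 36, 52 and 974 for the interactions of NIM811 (mean), CsA (12 h) and NIM811 (12 h). Over 24 and 48 h the interactions gave 4 and 0. A dim filter in the second set gave 1 for the CsA dose step in Clone A and 29 for CsA 5 µM at 24 h.

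Leaving out 1 array moved these counts by over 1.5 times, given as lowest and highest with the array left out (R for replicate). Lines at 24 h: 1410 (Clone A control R1) and 1868 (Huh7 control R1). CsA in Huh7: 52 (CsA R3) and 101 (control R1) at 12 h, 142 (control R3) and 357 (control R1) at 24 h, 47 (control R1) and 202 (control R3) at 48 h. NIM811 in Huh7: 62 (control R2) and 129 (control R1), 80 (NIM811 R3) and 143 (control R1), 36 (control R1) and 677 (control R2). CsA in Clone A: 1704 (control R3) and 3611 (CsA R2), 485 (CsA R1) and 696 (CsA R2), 46 (CsA R1) and 325 (CsA R3). NIM811 in Clone A: 2556 (control R3) and 4083 (NIM811 R1), 326 (control R3) and 435 (NIM811 R2), 59 (control R1) and 1343 (control R3). CsA against NIM811, from 0 by limma: 23 in Huh7 at 24 h (CsA R2), 25 in Clone A at 12 h (CsA R3) and 327 at 48 h (CsA R3). Interactions: CsA mean 5 (Huh7 CsA 24 h R1) and 11 (Huh7 control 12 h R3), NIM811 mean 0 (Huh7 NIM811 12 h R2) and 41 (Clone A control 48 h R3), CsA 12 h 6 (Clone A control R3) and 71 (Clone A CsA R3), CsA 24 h 0 (Huh7 control R1) and 12 (Huh7 CsA R2), NIM811 12 h 61 (Huh7 NIM811 R3) and 479 (Huh7 control R1), NIM811 24 h 1 (Huh7 control R3), NIM811 48 h 2 (Huh7 control R2). Second set: NIM811 5 µM in Huh7 9 (control R4), NIM811 5 µM in Clone A 0 (NIM811 R4) and 509 (control R4), CsA 5 µM at 24 h in Clone A 0 (control R4) and 863 (CsA R4), CsA dose step in Clone A 589 (CsA 5 µM R4).

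Lists turned direction in these cases, and none of the turned values passed 0.05. For CsA against NIM811, antigen presentation in Huh7 at 24 h was 0.0393 without CsA R2 and 0.550 without CsA R1. In Clone A at 12 h cholesterol synthesis was -0.11 without NIM811 R3, -0.06 without CsA R2 and 0.367 without CsA R3, and lipoproteins were -0.0809, -0.06 and 0.368. The proteasome list for CsA in Clone A at 48 h was 0.0452 without control R3 and -0.343 without CsA R3. With the score covariate, cholesterol synthesis was -0.0414 and the proteasome 0.0238 for CsA against NIM811 in Clone A at 48 h, and lipoproteins were 0.0168 for the CsA interaction at 12 h.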

Other observations

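Interferon-stimulated genes, which sensing of viral RNA can induce, were not raised as a list in untreated Clone A: the mean was -0.19 with 2 of 14 genes higher and 6 lower. The proteasome list there had 11 of 22 genes lower and none higher, the same counts when adjusted over the list alone (camera adjusted p = 0.0186, but adjusted p = 0.851 with an estimated correlation). The ribosome biogenesis list had 8 of 12 lower (9 adjusted over the list alone; adjusted p = 0.00982, but adjusted p = 0.772 with an estimated correlation).

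NIM811 at 48 h in Clone A also lowered 4 of 16 autophagy and lysosome genes and raised none (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00475, but adjusted p = 0.507 with an estimated correlation). The acute phase list, genes of secreted liver proteins, had 1 gene lower there (4 adjusted over the list alone), with a mean of -0.57 (adjusted p = 0.00475, but adjusted p = 0.507 with an estimated correlation). The matrix minus hepatocyte score moved in this comparison too, with means of -0.86 untreated and -0.14 with NIM811. At 12 h in Clone A CsA raised 3 of 9 immediate-early genes, which answer growth signals within minutes (5 adjusted over the list alone; adjusted p = 0.00633, but adjusted p = 0.554 with an estimated correlation).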
